A study of Homo sapiens with 16 samples.

How the data were processed

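Chromatin immunoprecipitation sequencing (ChIP-seq) was performed in PC-3M, a metastatic human prostate cancer cell line, with antibodies against histone H4 monomethylated at lysine 12 (H4K12me1), histone H4 trimethylated at lysine 20 (H4K20me3), and the enzyme subunits KMT9a and KMT9b. KMT9a is encoded by N6AMT1 and KMT9b by TRMT112. Cells had received a control siRNA or an siRNA against KMT9a (for the H4K12me1, H4K20me3 and KMT9a antibodies) or KMT9b (for the KMT9b antibody). The series holds 16 samples, of which 8 are ChIP libraries with a deposited peak list and 8 are input libraries, which were not analysed here. Each combination of antibody and siRNA was represented by 1 library and 1 peak list, so there were no replicates, no test was made between conditions and no p-value is given.

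Reads were mapped to hg19 with STAR, per the submitters' processing notes. The version and settings of the peak caller are not given in the sources used here. In 4 of the deposited lists the peaks carry the name MACS, numbered without gaps. These lists (H4K12me1 after knockdown, both H4K20me3 lists and KMT9b after knockdown) give a position and the authors' score, read as 10 times the negative log10 of the caller's p because its lowest value was 50. The KMT9a control, KMT9a knockdown and KMT9b control lists were deposited without a header in the column layout of a MACS table, with the whole-number tag count of each peak, the score, the fold enrichment over the caller's local background and a false discovery rate (FDR) in percent. The deposited H4K12me1 control list gives positions, lengths and 1 unlabelled value per peak, read as the FDR in percent because it ran from 5.20 to 9.99. All 4 deposited lists with a percent FDR held values under 10 and nothing above, while the 4 others had no such limit. FDR did not fall steadily as scores rose: in the KMT9a control list it was 0% at the highest score of 3110.18 but 9.76% at the next, 2101.55. The KMT9a knockdown list ended at a score of 335.65, and the KMT9b control list had no peak between 336.87 and 3100.55. The control and knockdown lists of H4K12me1 and of KMT9b were therefore filtered differently, the KMT9a lists were both filtered, and the H4K20me3 lists were both unfiltered. Sequencing depth is unknown, since tags inside peaks are not library totals.

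Positions were compared with the GRCh37 sequence, the assembly that hg19 represents; no peak reached beyond a chromosome end. Gene positions came from GENCODE 44 lifted to GRCh37. 1 canonical transcription start site (TSS) was used for each of 19856 protein-coding gene symbols, and a promoter was called occupied when a peak came within 1 kb of that TSS. Lists were compared by overlap of at least 1 bp. Each share is given with a 95% Wilson interval, which covers counting error only, and beside the mean of 100 random placements of the other list on the same chromosomes outside assembly gaps. GC content was computed for each peak. The share of repeat-masked bases, planned beforehand, was not computed because the reference used here held 0 lower-case bases.

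Before the data were examined, 27 gene lists were fixed: cell cycle and mitosis, DNA replication, DNA repair, glycolysis and pentose phosphate, citrate cycle, oxidative phosphorylation, mitochondrial ribosome, cytosolic ribosome, translation factors and tRNA synthetases, proteasome, splicing, nucleotide synthesis, serine, glycine and one-carbon metabolism, cholesterol and fatty acid synthesis, androgen receptor targets, TRMT112 and partner methyltransferases, canonical histone genes, zinc finger (ZNF) genes, protocadherin clusters, olfactory receptors, HOX genes, keratins, taste and defensin genes, blood cell markers, fibroblast and endothelial markers, liver, muscle and neuron markers, and transcription factor and mitogen response genes. The number of occupied promoters per list was ranked among 10000 random lists of the same size, matched on promoter GC content in 5 strata (within 500 bp of the TSS). This percentile describes these libraries and is not a test between conditions. Random lists were not matched on position. For lists whose genes lie side by side, such as keratins, HOX genes and protocadherins, the percentile can reflect the peak density of a few regions.

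The rule for named genes was also fixed beforehand. N6AMT1 and TRMT112 were always named. For each antibody the 10 genes with the highest-scoring control peak at the promoter and the 5 with the highest-scoring knockdown peak were taken, by width where the list had no score. From each gene list described, up to 4 members with the widest H4K12me1 control peak were taken (for ZNF genes, the highest H4K20me3 score). Of promoters with H4K12me1, KMT9a and KMT9b control peaks and no H4K12me1 peak after knockdown, the 10 with the widest H4K12me1 peak were taken. Gene models without a symbol were counted but are not named.

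Overlap counts were checked on simulated peak lists, where they equalled those of bedtools 2.31.1. Planted overlaps of 29.6% to 30.0% were found as 30.0% to 31.2%. Of 1000 simulated random gene lists of 40 genes, 6.1% lay above the 95th percentile, and a planted list reached percentile 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the required overlap, the score threshold, equal list lengths, merging of neighbouring peaks, chromosomes, regions with peaks of all 4 antibodies, TSS windows, gene models and random placement. Placement 5 to 250 kb from each peak's own position, with or without choosing the nearest GC content among 20 candidates, was added after the data were examined. When a list that had itself been placed in this way stood in for the real list, the GC-matched ratio was 1.04 to 1.08 rather than 1. Matching was incomplete: the median GC content was 56.0% for KMT9a peaks and 52.5% for their placed copies, 53.2% and 51.9% for KMT9b, and 48.9% and 47.7% for H4K20me3.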

Results

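ChIP-seq peak lists were available for 4 antibodies in PC-3M prostate cancer cells, each in control siRNA cells and after knockdown of an enzyme subunit. H4K12me1 is the mark that the series title assigns to the methyltransferase KMT9, a complex of KMT9a and KMT9b. H4K20me3, a mark of compact chromatin, served as a second histone H4 methylation. The control lists held 48390 peaks for H4K12me1, 107965 for H4K20me3, 25333 for KMT9a and 60853 for KMT9b. The knockdown lists held 2843, 189114, 38967 and 16339 peaks in the same order. The summed peak length in control cells was 33.2 Mb for H4K12me1, 172 Mb for H4K20me3, 34.1 Mb for KMT9a and 38.6 Mb for KMT9b. Every list came from 1 library without a replicate, so differences between lists could not be set against replicate spread. Scores, folds and tag counts of peaks are the authors' values and were used to rank or describe peaks within a list. The exception is KMT9a, whose control scores were also set against the highest score of its knockdown list.

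The targeted genes were examined first. The promoter of N6AMT1, which encodes KMT9a (hg19 chromosome 21, TSS at 30257689), had a KMT9a peak in control cells from 30257073 to 30258045, with 17 tags, a 6.54-fold enrichment and a score of 174.60. After KMT9a knockdown the same promoter had a KMT9a peak from 30257283 to 30257914 with 10 tags, a 6.25-fold enrichment and a score of 125.11. After KMT9b knockdown it had a KMT9b peak with a score of 53.90, and no KMT9b peak was listed there in control cells. The promoter of TRMT112, which encodes KMT9b (chromosome 11, TSS at 64085031), had KMT9a peaks in control cells (64084284 to 64085562, 5.45-fold, score 219.01) and after KMT9a knockdown (64084529 to 64085031, 7.14-fold, score 244.93). An H4K20me3 peak came within 1 kb of the TRMT112 TSS after knockdown, from 64082219 to 64084153. Neither promoter had an H4K12me1 peak in either list. Peaks at a gene's promoter do not measure its RNA or protein, so the lists hold no check of knockdown efficiency.

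The first comparison asked whether H4K12me1 depended on KMT9a. In control cells H4K12me1 lay mostly in gene bodies and between genes, as randomly placed peaks did, and 2425 promoters carried a peak. After KMT9a knockdown 9 promoters carried a peak, a log2 ratio of −8.07, and the number of peaks changed by −4.09 on the log2 scale. The widest promoter peaks in control cells covered SCX, a transcription factor of tendon development (chromosome 8, 145306353 to 145326124), ZSWIM8, a substrate receptor of a ubiquitin ligase (chromosome 10, 75544791 to 75556202), and TG, the thyroid hormone precursor thyroglobulin (chromosome 8, 133878701 to 133887519). CYFIP2, a subunit of the actin-regulating WAVE complex (chromosome 5, 156692438 to 156696139), HELZ2, a helicase and transcriptional coactivator, SYNPO2L, the annexin ANXA7 and the Rho exchange factor ARHGEF35 followed. TBC1D3B and TBC1D3E shared a 13527 bp peak on chromosome 17, and as near-identical paralogs they can exchange reads. ZSWIM8, SYNPO2L and ANXA7 lie on chromosome 10 from 45 to 85 Mb, where all 8 lists were dense. The 5 Mb of chromosome 8 starting at 140000001, just before SCX, held 630 H4K12me1, 851 H4K20me3, 382 KMT9a and 937 KMT9b control peaks. The ranking of these promoters by width can therefore follow regions dense in peaks. None of these 10 promoters had an H4K12me1 peak after knockdown, and of all 2425 promoters with a control peak only 1 had. With a TSS window of 3 kb, 4192 promoters had a peak in control cells and 18 after knockdown.

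Of the 48390 control H4K12me1 peaks, 21 (0.0434%, interval 0.0284 to 0.0663) met a knockdown peak, against 0.262% with random placement and 0.126% with GC-matched placement nearby. Of the 2450 control peaks at a TSS, 0 met a knockdown peak, which allows a share of up to 0.157%. Peaks at a TSS were 5.06% of the control list (interval 4.87 to 5.26, random 2.19%). Introns held 44.6% (random 44.1%), and 45.1% lay between genes (random 51.1%). In the knockdown list 0.352% lay at a TSS (interval 0.191 to 0.646, random 2.28%) and 81.4% between genes (random 52.7%). The median GC content of the peaks was 52.8% in the control list and 35.6% in the knockdown list, against 41.0% and 40.4% at random. Of the knockdown peaks, 1662 (58.5%) lay within 5 Mb of an assembly gap of at least 1 Mb, against 7.18% of the control peaks. The knockdown promoters with the highest scores were TNFSF18, the ligand of the T cell receptor GITR, FILIP1L, and the olfactory receptors OR4F3, OR11H12 and OR6F1. In all, 6 of 404 olfactory receptor promoters had a knockdown H4K12me1 peak, where GC-matched random lists averaged 0.774; OR4F3 and OR11H12 belong to families of near-identical copies that can exchange reads. The control list was limited to an FDR under 10% and the knockdown list was not, so filtering can only have shortened the control list.

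The H4K12me1 control list held no peaks of very low FDR, so its strongest peaks may be missing. The counts and percentiles below describe the listed peaks only. A low count therefore does not show that the mark was absent from those genes. Among the gene lists, H4K12me1 in control cells exceeded GC-matched lists most at liver, muscle and neuron markers, keratins and HOX genes. Olfactory receptors, taste and defensin genes and protocadherins ranked low among GC-matched lists. It occupied 9 of 28 promoters of liver, muscle and neuron markers (3.08 expected from GC-matched lists, percentile 99.8), among them TNNT3 of skeletal muscle troponin, the liver cytochrome CYP2E1, the glutamate receptor subunit GRIN1 and the neuroendocrine granule protein CHGA. It occupied 11 of 55 keratins (5.31 expected, percentile 98.9), including KRT6B, KRT4, KRT84 and KRT5. HOX genes had 9 of 39 promoters occupied (4.96 expected, percentile 96.5), including HOXB8, HOXB9, HOXD10 and HOXB6. The 4 named keratins lie close together on chromosome 12, as do HOXB8, HOXB9 and HOXB6 on chromosome 17. The percentiles of these lists can therefore reflect the peak density of single regions. Androgen receptor targets had 4 of 18 promoters occupied (percentile 86.3): SLC45A3, PMEPA1, FKBP5 and KLK3, which encodes prostate-specific antigen. Cell cycle and mitosis genes had 6 of 65 promoters occupied (8.17 expected, percentile 21.5), including the condensin subunit SMC2, the mitotic kinases PKMYT1 and PLK1, and CDK4. DNA replication (POLE and GINS2) and DNA repair (XRCC3 and RAD51) had 2 occupied promoters each, at percentiles 3.93 and 4.77. Metabolic lists lay near their random expectation, with 3 of 29 glycolysis and pentose phosphate genes (HK1, HK2 and TKT), 3 of 29 citrate cycle genes (SDHB, DLST and SDHD), 7 of 78 oxidative phosphorylation genes (among them CYC1, COX4I2, NDUFA4L2 and ATP5ME) and 5 of 35 cholesterol and fatty acid genes (among them FASN, MVD, INSIG1 and FDPS). The same held for 3 of 29 nucleotide synthesis genes (TYMS, UMPS and RRM2B), 3 of 23 serine, glycine and one-carbon genes (GCSH, PHGDH and MTRR), 10 of 79 cytosolic ribosome genes (among them RPS24, RPL36, RPL28 and RPL38) and 8 of 77 mitochondrial ribosome genes (among them MRPS16, MRPL12, MRPL23 and MRPL34). Translation factors had 7 of 74 occupied (EIF5 and EIF2S2, and EIF3C and EIF3CL, which are near-identical copies), the proteasome 4 of 39 (PSMC1, PSMA6, PSMD5 and PSMD12) and splicing 4 of 46 (SRSF6, SRSF2, SNRPB and PRPF3). Mitogen response genes had 4 of 24 occupied (KLF10, IER3, CCN2 and ATF3), blood cell markers 4 of 30 (PRF1, CD79B, CSF1R and CD8B), fibroblast and endothelial markers 2 of 20 (CLDN5 and THY1; percentile 52.8), canonical histone genes 2 of 64 (H2BC18 and H4C12), ZNF genes 67 of 504, and olfactory receptors 15 of 404 (percentile 5.33; among them OR2T5, OR2T29, OR2W3 and OR1J2). Taste and defensin genes had 2 of 69 occupied (TAS2R5 and the multi-copy DEFA1; percentile 18.2), protocadherins 0 of 49 (percentile 2.81) and the TRMT112 partners 0 of 7.

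**Figure D1:**
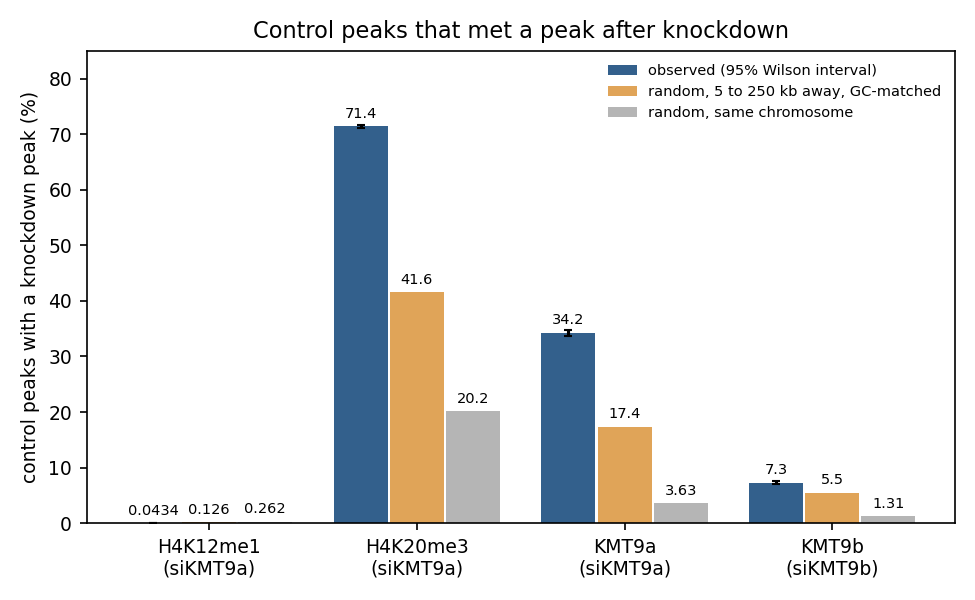
Share of control peaks (percent, vertical axis) that met a peak of the same antibody after knockdown, for the 4 antibodies with the siRNA in parentheses; blue bars are observed with 95% Wilson intervals, orange bars are GC-matched random placements 5 to 250 kb away and grey bars random placements on the same chromosome. H4K20me3 kept 71.4% and KMT9a 34.2% of control peaks, while KMT9b kept 7.30% and H4K12me1 0.0434%.

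The second comparison asked how the KMT9a list changed when KMT9a itself was knocked down. KMT9a in control cells occupied 9485 promoters, among them nearly all those of cytosolic and mitochondrial ribosome genes, and 5315 promoters were occupied after knockdown (log2 ratio −0.84). The list nevertheless grew from 25333 to 38967 peaks (log2 ratio 0.62), while the summed length changed by −0.65 on the log2 scale and the median width went from 1061 to 479 bp. At promoters the highest control score was at the TSSs of the splicing factor HNRNPH3 and of PBLD on the opposite strand (chromosome 10, 70090496 to 70093216, 17.06-fold). Also among the 10 highest promoters were RPS24 and RPS5, both small ribosomal subunit proteins, and the zinc finger genes ZNF827 and ZNF407. The splicing factor RBM39, the histone demethylase PHF2, the transcription factor TFAP4 and RHOBTB1 made up the rest. None of these 10 promoters had a KMT9a peak in the knockdown list. The highest knockdown scores at promoters were at HIF1A, the oxygen-regulated transcription factor (chromosome 14, 62162081 to 62163355, score 335.65), the elongation factor IWS1, YIPF4, DNPH1 and the laminin chain LAMA5. All of these also had a control peak.

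Of the control KMT9a peaks, 8676 (34.2%, interval 33.7 to 34.8) met a knockdown peak, against 3.63% at random and 17.4% with GC-matched placement nearby. At a TSS 3710 of 8632 control peaks met a knockdown peak (43.0%), and elsewhere 4966 of 16701 (29.7%). When 50% of the control peak had to be covered, the share of all control peaks was 11.7%. TSS peaks were 34.1% of the control list (interval 33.5 to 34.7; random 2.72%) and 13.8% of the knockdown list (interval 13.5 to 14.2; random 2.06%). In the decile of control peaks with the highest scores 82.5% lay at a TSS, and in the lowest decile 5.63%. The share that met a knockdown peak was 54.3% in decile 9 and 42.8% in decile 10. The knockdown list held no peak with a score above 335.65, whereas decile 10 of the control scores began at 441.68, so the absence of the highest control promoters from it cannot be separated from the FDR filter. With control peaks limited to the knockdown list's range of scores, 5991 promoters were occupied in control cells.

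KMT9a occupied 77 of 79 cytosolic ribosome promoters in control cells, where GC-matched lists averaged 37.4, and 29 after knockdown (20.8 expected). The mitochondrial ribosome had 72 of 77 promoters occupied in control cells and 31 after knockdown (20.3 expected), all 31 occupied in both lists. Oxidative phosphorylation genes went from 65 to 38 of 78 (20.9 expected after knockdown). Translation factors and tRNA synthetases went from 63 to 29 of 74 (21.3 expected after knockdown). Splicing genes went from 40 to 23 of 46, and the proteasome from 31 to 17 of 39. Each of these control counts lay at or above percentile 99.9. After knockdown, both ribosome lists, oxidative phosphorylation and translation factors still exceeded GC-matched lists, at percentiles 97.4 to 100. Occupied promoters as a whole went from 9485 to 5315, and the knockdown list held no score above 335.65. All 7 genes of the list of TRMT112 and its partner methyltransferases were occupied in control cells (2.72 expected) and 6 after knockdown. Cholesterol and fatty acid synthesis (28, then 10 of 35), nucleotide synthesis (23, then 13 of 29), serine, glycine and one-carbon metabolism (18, then 12 of 23) and the citrate cycle (22, then 11 of 29) lay at percentiles 98.4 to 99.8 in control cells. Glycolysis (20, then 12 of 29), DNA replication (27, then 11 of 46), mitogen response genes (16, then 12 of 24) and histone genes (20, then 10 of 64) lay between percentiles 77.3 and 86.8, and DNA repair (29, then 16 of 45) lay above them; among unmatched lists the histone count lay at percentile 0.37. Cell cycle and mitosis genes were at their expectation, with 31 of 65 in control cells (33.6 expected) and 17 after knockdown. ZNF genes had 291 of 504 occupied in control cells (247 expected) and 166 after knockdown.

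KMT9a was scarce in control cells at several other gene lists. It occupied 2 of 404 olfactory receptors (52.1 expected), 1 of 49 protocadherins, 1 of 69 taste and defensin genes, 7 of 39 HOX genes (percentile 0), 5 of 55 keratins (20.4 expected), 3 of 30 blood cell markers, 3 of 20 fibroblast and endothelial markers, and 1 of 28 liver, muscle and neuron markers. After knockdown the counts were 10, 0, 3, 9, 6, 6, 2 and 5 in the same order. Androgen receptor targets had 6 of 18 promoters occupied in control cells (9.05 expected, percentile 6.26) and 4 after knockdown. The peak lists do not show whether these targets were active in PC-3M cells.

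**Figure D2:**
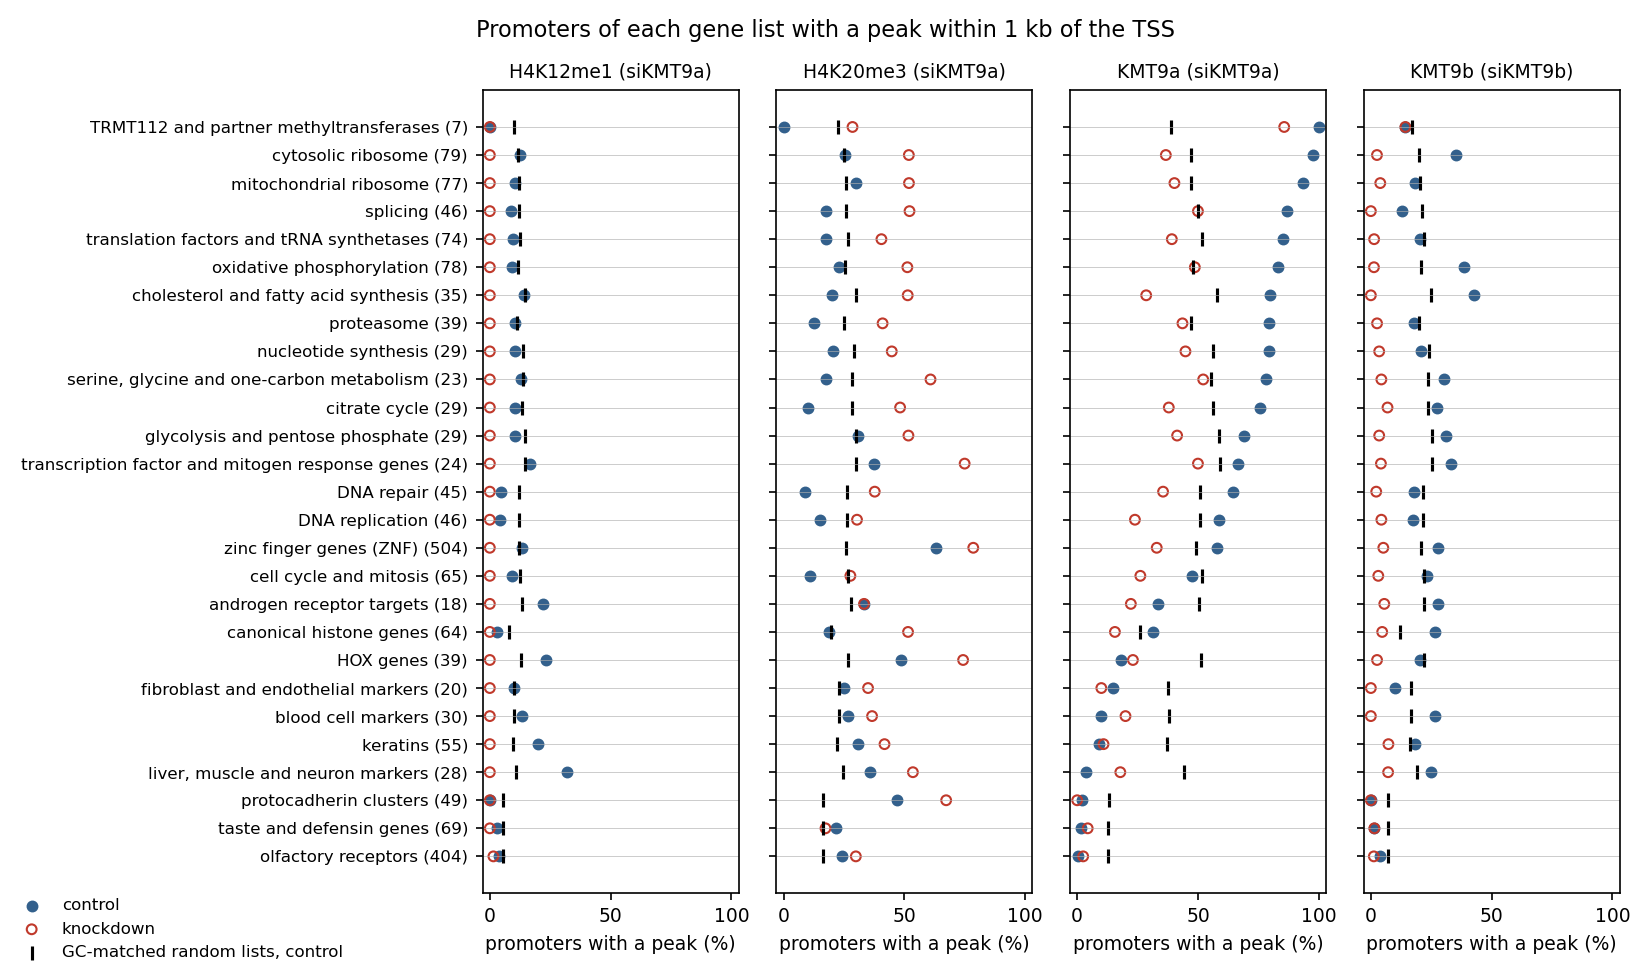
Percent of promoters with a peak within 1 kb of the TSS (horizontal axis) for the 27 gene lists (lines, with the number of genes), 1 panel per antibody; filled blue points are control cells, open red points the knockdown named in the panel title, and black ticks the mean of GC-matched random lists for control cells. Cytosolic ribosome genes reached 97.5% for KMT9a in control cells, and ZNF genes 63.1% for H4K20me3.

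The third comparison concerned KMT9b before and after its own knockdown. KMT9b in control cells occupied 4126 promoters and after knockdown 792 (log2 ratio −2.38), and the number of peaks changed by −1.90 on the log2 scale. The highest control score in the list, 3218.44, did not lie at a promoter. At promoters the highest was at ELOVL1, an elongase of very long fatty acids (chromosome 1, 43833774 to 43834677, score 336.54). The deubiquitinase gene USP38, GARIN5B, the epithelial sodium channel subunit SCNN1A, SSBP3, ZNF700, ZNF446, the peroxiredoxin PRDX6 and the receptor tyrosine kinase EPHA2 followed. The ELOVL1 peak had an FDR of 9.97%, close to the limit of 10%. The control list held no peak with a score between 336.87 and 3100.55, so stronger KMT9b promoters may have been filtered out. None of the promoters named here, nor that of a gene model without a symbol beside ZNF700, had a KMT9b peak after knockdown. Of all 4126 promoters with a control peak, 302 (7.32%) had one. The highest knockdown scores at promoters were at KMT2A, a histone H3 lysine 4 methyltransferase (chromosome 11, 118306451 to 118307841), SNX12, ZNF76, the gamma-tubulin complex gene TUBGCP5 and the mitochondrial chaperonin HSPD1.

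Of the control KMT9b peaks, 4442 (7.30%, interval 7.10 to 7.51) met a knockdown peak, against 1.31% at random and 5.50% with GC-matched placement nearby. At a TSS the share was 5.41% (interval 4.78 to 6.12) and elsewhere 7.45% (interval 7.23 to 7.67). TSS peaks were 7.23% of the control list (interval 7.03 to 7.44; random 2.23%) and 4.65% of the knockdown list (interval 4.34 to 4.99; random 2.24%). Enrichment was low in the control list, with a median of 2.50-fold, and 1112 peaks (1.83%) had a fold below 1. The control list was filtered on FDR and the knockdown list was not.

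KMT9b occupied 30 of 78 oxidative phosphorylation promoters in control cells (16.1 expected) and 1 after knockdown (2.99 expected). At cytosolic ribosome promoters it occupied 28 of 79 (15.8 expected) and then 2 (2.93 expected). Histone genes had 17 of 64 promoters occupied and then 3; the control count was extreme among GC-matched lists (7.60 expected) but lay at percentile 86.8 of unmatched ones (13.3 expected). With the upper part of the control list by score, oxidative phosphorylation had 19. Cholesterol and fatty acid synthesis went from 15 of 35 (8.71 expected) to 0, and ZNF genes from 141 of 504 (106 expected) to 26. Protocadherins (0 of 49), olfactory receptors (16 of 404) and taste and defensin genes (1 of 69) lay at percentiles 0.435 to 2.44. The other lists lay between percentiles 8.61 and 92.1.

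The fourth comparison concerned H4K20me3 after KMT9a knockdown. H4K20me3 covered zinc finger genes in both lists, and its list was the one that grew most, from 107965 to 189114 peaks (log2 ratio 0.81), with 5246 promoters occupied in control cells and 9381 after knockdown (log2 ratio 0.84). Of 504 ZNF promoters, 318 had a peak in control cells (131 expected), 396 after knockdown (236 expected) and 313 in both. Among control peaks at promoters, the highest named were at KIAA1143 and KIF15, a mitotic kinesin, which share a divergent promoter (chromosome 3, 44796739 to 44803539), and at ZNF614 (chromosome 19, 52525214 to 52532554). The other 7 were gene models without a symbol on chromosome 19, tied at a score of 3100 with ZNF12, ZNF134 and ZNF136; 140 control peaks in all reached that score, and 43 promoters had such a peak. After knockdown the highest named promoters were NRBF2, an autophagy gene (chromosome 10, 64889752 to 64894045), the zinc finger genes ZFP90 and ZIK1, and DOK6, an adaptor of receptor tyrosine kinases.

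Of the control H4K20me3 peaks, 77128 (71.4%, interval 71.2 to 71.7) met a knockdown peak, against 20.2% at random and 41.6% with GC-matched placement nearby. The share rose with the control score, from 44.7% in the lowest decile to 98.9% in the highest. TSS peaks were 4.94% of the control list (interval 4.81 to 5.07; random 2.76%) and 5.28% of the knockdown list (interval 5.18 to 5.39; random 2.53%). H4K20me3 also lay at the protocadherin clusters, neuronal adhesion genes in tandem arrays, with 23 of 49 promoters in control cells (7.96 expected) and 33 after knockdown. It lay at 19 then 29 of 39 HOX genes (10.5 and 18.9 expected). Olfactory receptors had 98 then 121 of 404 promoters occupied, above GC-matched lists (65.4 expected in control cells, percentile 98.4 after knockdown) but below unmatched ones, which averaged 107 and 191. Histone genes went from 12 (12.5 expected) to 33 of 64 (20.9 expected from GC-matched and 30.2 from unmatched lists), and mitogen response genes from 9 to 18 of 24 (7.16 and 13.1 expected). Cell cycle and mitosis genes had fewer peaks than GC-matched lists in both conditions, with 7 of 65 (17.4 expected) and 18 of 65 (31.4 expected). DNA repair genes went from 4 to 17 of 45 (11.8 and 21.3 expected). The numbers of peaks depend on depth, which is unknown, so the longer knockdown list is not by itself a gain of the mark.

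The last comparison set the antibodies against each other in control cells, to see whether the subunits of KMT9 lay where H4K12me1 did. Promoters with peaks of H4K12me1, KMT9a and KMT9b numbered 591, where 241 would be expected if the lists were independent. That expectation takes no account of GC content or of the 2794 promoters that KMT9a and KMT9b shared. KMT9a, with or without KMT9b, was present at 50.6% of promoters with H4K12me1, against 55.0% of GC-weighted promoters without H4K12me1. The excess is therefore not by itself a sign that both subunits lay where H4K12me1 did. Among the 591 promoters, the widest H4K12me1 peaks were at ZSWIM8, CYFIP2, HELZ2, NUTM2D (a member of a near-identical family), TEDC1 and RPS24. The divergent promoter of the chaperone regulator BAG5 and COA8, and METTL13, a lysine methyltransferase of an elongation factor, followed. Of these, ZSWIM8 and RPS24 lie on chromosome 10 from 45 to 85 Mb, where all lists were dense. At RPS24 (chromosome 10, TSS at 79793621) the H4K12me1 peak lay from 79791445 to 79793294, upstream of the TSS, and the KMT9a peak from 79793001 to 79794805 across it. At METTL13 (chromosome 1, TSS at 171750800) the H4K12me1 peak from 171750176 to 171751866 lay within the KMT9a peak from 171748638 to 171752483. KMT9b enrichment at these promoters ran from 0.91-fold at NUTM2D, 1.24-fold at ZSWIM8 and 1.37-fold at RPS24 to 2.20-fold at BAG5 and COA8 and 2.55-fold at HELZ2, against a median of 2.50-fold in the control list.

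Of the H4K12me1 peaks, 9.39% met a KMT9a peak (interval 9.14 to 9.66; random 2.48%), 18.4% a KMT9b peak (interval 18.1 to 18.8; random 4.08%) and 17692 peaks (36.6%; random 10.8%) an H4K20me3 peak. A peak of either subunit met 11703 H4K12me1 peaks (24.2%), and peaks of both met 1763 (3.64%). Of the KMT9a peaks, 32.3% met a KMT9b peak (interval 31.8 to 32.9; random 6.07%). Placed on the same chromosome, random peaks gave ratios of observed to random overlap of 3.79 for H4K12me1 with KMT9a, 4.51 with KMT9b, 3.40 with H4K20me3, and 5.33 for KMT9a with KMT9b. With GC-matched placement 5 to 250 kb away the same ratios were 1.06, 1.25, 1.41 and 1.39, and lists that had themselves been placed gave 1.04 to 1.08. Placed peaks remained lower in GC content than the real peaks, so GC content was not fully accounted for. For H4K20me3, the ratio fell from 2.65 to 1.17 with KMT9a and from 2.60 to 1.195 with KMT9b.

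At promoters KMT9a was present at 50.6% of promoters with H4K12me1 (interval 48.6 to 52.5) and at 47.4% of those without (interval 46.6 to 48.1), which became 55.0% when weighted to the same GC content. KMT9b was present at 38.1% of promoters with H4K12me1 (interval 36.2 to 40.1) and 21.3% of GC-weighted promoters without. H4K20me3 was present at 52.7% of promoters with H4K12me1 (interval 50.7 to 54.7) and 25.0% of GC-weighted promoters without. KMT9b was present at 29.5% of promoters with KMT9a (interval 28.5 to 30.4) and 17.2% of GC-weighted promoters without. At promoters with H4K20me3, KMT9b was present at 35.3% (interval 34.1 to 36.6) against 17.7% of GC-weighted promoters without, and KMT9a at 49.9% (interval 48.5 to 51.2) against 53.5%.

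**Figure D3:**
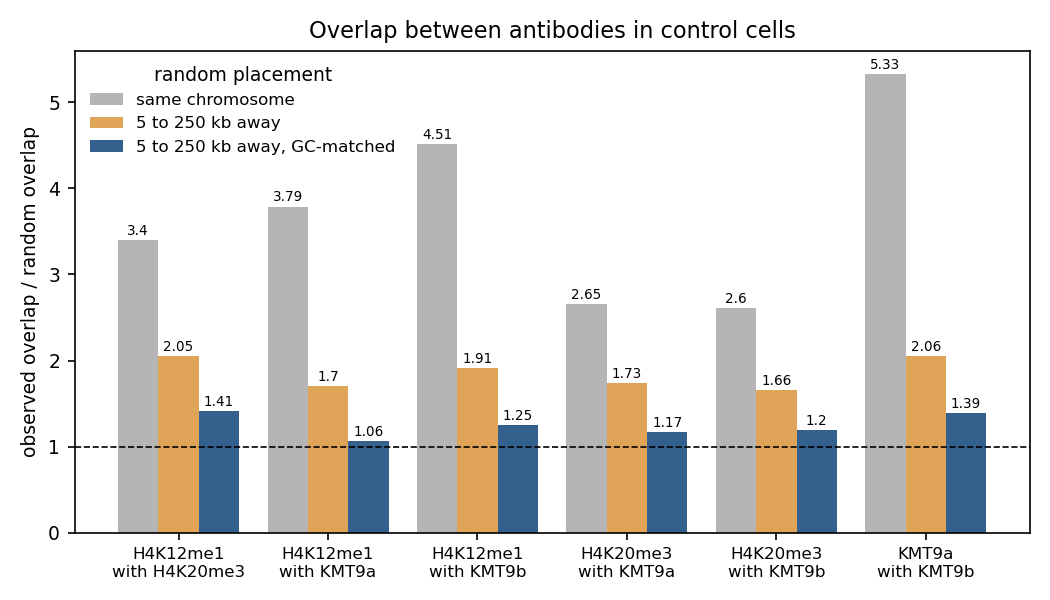
Ratio of observed to random overlap (vertical axis) for the 6 pairs of control lists, with the second list placed at random on the same chromosome (grey), 5 to 250 kb away (orange) or 5 to 250 kb away with matched GC content (blue); the dashed line marks a ratio of 1. H4K12me1 with KMT9a falls from 3.79 to 1.06.

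**Figure D4:**
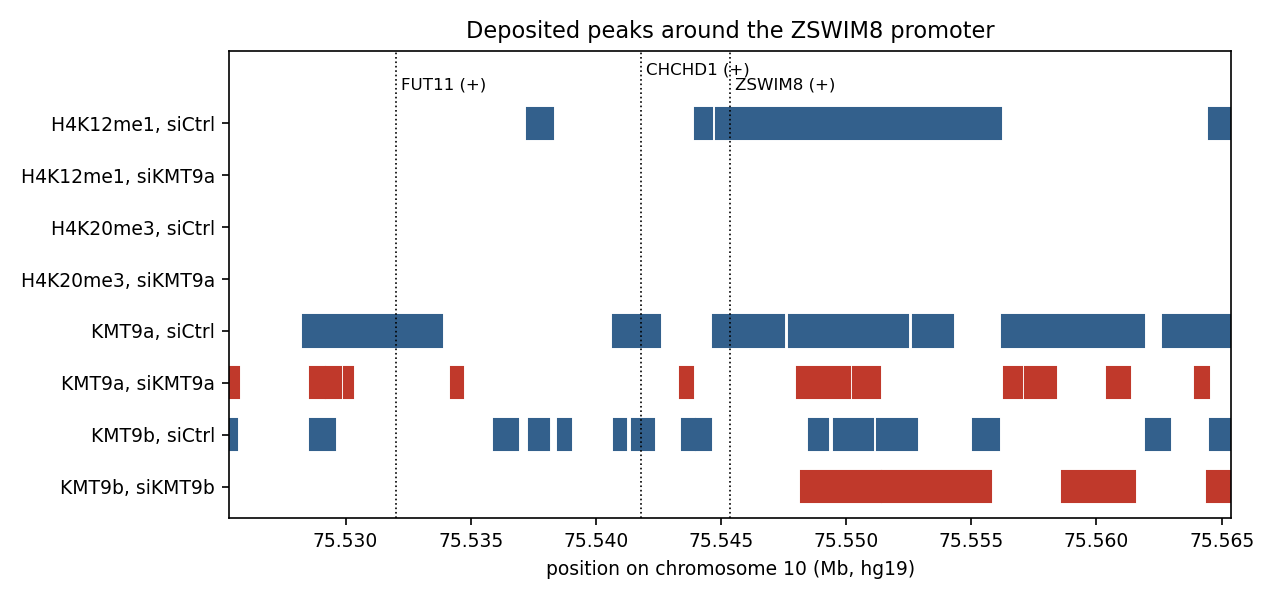
Deposited peaks (boxes) of the 8 lists around the ZSWIM8 promoter on chromosome 10 (horizontal axis, hg19 position in Mb), with control cells in blue, knockdown in red and dotted lines at the TSSs of FUT11, CHCHD1 and ZSWIM8, all on the plus strand. The H4K12me1 control peak from 75544791 to 75556202 has no counterpart in the H4K12me1 knockdown list, and neither H4K20me3 list has a peak in the window.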

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

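Of the tests in this part, those of GC bias, of repeats next to assembly gaps, of overlap by knockdown score and of split peaks were written before their values were known, and the others were chosen after the results had been seen. Under the same KMT9a siRNA, the lists of different antibodies changed in opposite directions, which is what singled out these results. The log2 ratio of the number of peaks, knockdown over control, was −4.09 for H4K12me1, 0.81 for H4K20me3 and 0.62 for KMT9a. The log2 ratio of occupied promoters was −8.07 for H4K12me1, 0.84 for H4K20me3 and −0.84 for KMT9a. With 1 library per group, the difference between antibodies was not tested.

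H4K12me1 peaks were fewer and lay elsewhere after KMT9a knockdown. The FDR filter on the control list cannot explain the lower number. It can only have shortened that list, which was still 17.0 times longer than the unfiltered one. That follows from the direction of the filter and is not a test. The filter was not excluded as the cause of the new positions. Knockdown peaks met a control peak equally rarely with scores from the median up (0.772%) and below it (0.775%). The control list held no peak of FDR near 0, so its strongest peaks may be missing. Lower depth of the knockdown library stays open for the same reason, although 0.774% of knockdown peaks met a control peak, against 4.30% at random. Repeats next to assembly gaps did not account for the low GC content of the knockdown peaks. Their median GC content was 35.2% for the 1181 away from gaps, 35.7% near gaps and 40.4% at random. GC bias of the knockdown library or its input stays open. A bias that only hid GC-rich sites should have spared control peaks of low GC content. Of 129 such peaks, 0 met a knockdown peak (upper limit 2.89%). At random 0.262% of control peaks met one, so the test cannot exclude a bias that added low-GC background elsewhere. Loss of the mark with its writer and an immunoprecipitation that did not work in the knockdown library also stay open, and 1 library cannot separate them.

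The KMT9a list was longer but had fewer promoters after knockdown. An FDR filter that removed the highest-scoring knockdown peaks fits: from decile 9 to decile 10 of the control scores the share of peaks met by a knockdown peak changed by −11.6 percentage points, where H4K20me3, unfiltered, kept rising. Splitting of knockdown peaks into pieces was excluded, as the ratio of merged knockdown to merged control peaks was still 1.45. Loss of KMT9a from promoters after its own knockdown, the biological explanation, was not tested and stays open: with control scores held to the knockdown range, 5991 control promoters stood against 5315 after knockdown, from 1 library each and at unknown depth.

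Peak lists of different antibodies overlapped. Shared density of peaks along chromosomes was excluded as the whole cause, since the lowest ratio with placement 5 to 250 kb away was 1.66. Shared density with GC content fits for H4K12me1 with KMT9a, whose GC-matched ratio of 1.06 lay within the 1.04 to 1.08 found for lists that had themselves been placed. This explanation stays open for H4K12me1 with H4K20me3 (1.41) and KMT9b (1.25), H4K20me3 with KMT9a (1.17) and KMT9b (1.195), and KMT9a with KMT9b (1.39). Their ratios lay above that range, but the placed peaks did not reach the GC content of the real ones. The median was 52.5% against 56.0% for KMT9a, 51.9% against 53.2% for KMT9b and 47.7% against 48.9% for H4K20me3. Whether KMT9a and KMT9b sites carry H4K12me1 rather than H4K20me3 stays open, because the answer turned on the placement: the ratio of H4K12me1 to H4K20me3 enrichment was 0.908 with KMT9a and 1.05 with KMT9b under GC-matched placement, but 1.43 and 1.73 under placement on the same chromosome.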

How the results depend on the processing

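The placements 5 to 250 kb away, the removal of regions near assembly gaps or on chromosome 10, and the limit on control scores were chosen after the results had been seen; the other alternatives were fixed before. Of 653 recomputed values, 412 stayed the same and 241 moved. Shares were held to their counting error and counts to 1.5 times the reported count. Ratios of observed to random overlap were held to their standard deviation over 100 random placements. Some moves were fixed in advance: GC-matched ratios were given no tolerance, and the upper 50% of a list by score always holds fewer peaks. The tally is therefore not a measure of robustness. None of the ratios of observed to random overlap crossed 1. The ratio of H4K12me1 to H4K20me3 enrichment with KMT9a did, from 1.43 to 0.908 with GC-matched placement. The order of some pairs of values did change: H4K20me3 had the higher share at a TSS after knockdown, but with the TSSs of all annotated genes in control cells, and H4K20me3 peaks met KMT9b more often than KMT9a, but less often when 50% of the peak had to be covered. Of 378 counts for gene lists that the report does not lead with, 284 stayed within 1.5 times. No paired analysis was possible because each group had 1 library. Unknown depth limits every comparison of list lengths. For the H4K12me1 control list, the upper part by score and equal numbers of peaks were not run because it has no score, and the repeat-masked share was not run because the reference has 0 lower-case bases. Except where an alternative by its construction takes fewer peaks or a wider or narrower window, the cause of a move was not tested.

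When 50% of the first peak had to be covered, the share of control peaks with a knockdown peak was 0.0248% for H4K12me1, 64.7% for H4K20me3, 11.7% for KMT9a and 6.09% for KMT9b; between antibodies it was 32.9% for H4K12me1 with H4K20me3, 7.22% with KMT9a and 12.1% with KMT9b, 4.39% for H4K20me3 with KMT9a and 3.56% with KMT9b, and 14.3% for KMT9a with KMT9b. When the midpoint of the first peak had to be covered, the same 10 values in the same order were 0.0248%, 64.5%, 20.9%, 6.08%, 32.7%, 7.20%, 12.3%, 5.43%, 7.49% and 18.2%. With equal numbers of peaks, the share kept after knockdown was 58.6% for H4K20me3, 26.3% for KMT9a and 8.69% for KMT9b, and between antibodies 16.0% for H4K20me3 with KMT9a, 20.7% for H4K20me3 with KMT9b and 16.3% for KMT9a with KMT9b.

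With the upper 50% of each list by score, the share kept was 75.8% for H4K20me3, 32.4% for KMT9a and 4.65% for KMT9b, and between antibodies 5.52% for H4K20me3 with KMT9a, 13.1% for H4K20me3 with KMT9b and 20.9% for KMT9a with KMT9b. By construction the lists then held 1424 (H4K12me1 knockdown), 53988 and 94563 (H4K20me3 control and knockdown), 12669 and 19503 (KMT9a) and 30452 and 8174 peaks (KMT9b). Occupied promoters were 3 for H4K12me1 after knockdown, 3148 for H4K20me3 in control cells, and 2653 and 433 for KMT9b. The share of peaks at a TSS was 5.69% and 6.78% for H4K20me3, 57.0% and 20.1% for KMT9a and 8.64% and 5.03% for KMT9b, and the median GC content 49.6% and 50.1%, 59.3% and 57.4%, and 54.8% and 51.8% in the same order. Oxidative phosphorylation promoters with a KMT9b control peak numbered 19.

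With peaks closer than 1 kb merged, the share kept was 71.1% for H4K20me3 and 7.06% for KMT9b, and between antibodies 19.1% for H4K12me1 with KMT9b, 9.52% for H4K20me3 with KMT9a and 17.1% for H4K20me3 with KMT9b. Without regions with peaks of all 4 antibodies, the share kept was 71.1% for H4K20me3, 33.6% for KMT9a and 7.09% for KMT9b; between antibodies it was 34.6% for H4K12me1 with H4K20me3, 7.31% with KMT9a and 16.6% with KMT9b, 7.99% for H4K20me3 with KMT9a and 15.5% with KMT9b, and 29.8% for KMT9a with KMT9b; the share at a TSS in control cells was 4.78% for H4K12me1, 4.78% for H4K20me3 and 34.7% for KMT9a.

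The share of peaks at a TSS, control then knockdown, was 3.59% and 0.0703% for H4K12me1, 4.30% and 4.56% for H4K20me3, 32.8% and 11.9% for KMT9a and 5.50% and 3.46% for KMT9b with a window of 500 bp. It was 9.94% and 0.915%, 7.54% and 8.29%, 38.2% and 18.6%, and 12.7% and 8.55% with a window of 3 kb, and 10.3% and 2.88%, 11.0% and 10.6%, 41.5% and 19.8%, and 13.0% and 11.1% with the TSSs of all annotated genes. H4K12me1 knockdown promoters numbered 2 with the window of 500 bp and 18 with that of 3 kb, where H4K12me1 control promoters numbered 4192 and KMT9b knockdown promoters 1433.

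With random placement within 5 kb of TSSs, the ratio of control peaks kept to random was 0.0900 for H4K12me1, 7.61 for H4K20me3, 2.36 for KMT9a and 2.81 for KMT9b, and the ratio between antibodies 2.54 for H4K12me1 with KMT9a, 3.48 for H4K12me1 with KMT9b, 2.69 for H4K20me3 with KMT9a, 3.30 for H4K20me3 with KMT9b and 1.59 for KMT9a with KMT9b. With placement 5 to 250 kb away, the ratio kept was 0.149 for H4K12me1, 2.36 for H4K20me3, 3.33 for KMT9a and 1.95 for KMT9b, and between antibodies 2.05 for H4K12me1 with H4K20me3, 1.70 with KMT9a and 1.91 with KMT9b, 1.73 for H4K20me3 with KMT9a and 1.66 with KMT9b, and 2.06 for KMT9a with KMT9b. With GC-matched placement the same 10 ratios in the same order were 0.345, 1.72, 1.97, 1.33, 1.41, 1.06, 1.25, 1.17, 1.195 and 1.39.

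Without regions within 5 Mb of assembly gaps of at least 1 Mb, the share kept was 0.0267% for H4K12me1, 70.9% for H4K20me3, 33.3% for KMT9a and 6.70% for KMT9b, and the H4K12me1 knockdown list held 1181 peaks. Without chromosome 10 from 45 to 85 Mb, the share kept was 33.4% for KMT9a and 6.72% for KMT9b, and between antibodies 9.05% for H4K12me1 with KMT9a, 17.7% for H4K12me1 with KMT9b, 8.60% for H4K20me3 with KMT9a, 15.8% for H4K20me3 with KMT9b and 31.0% for KMT9a with KMT9b. With KMT9a control scores up to the highest knockdown score, the share kept was 31.9%, the share at a TSS 25.8% and the number of occupied promoters 5991.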

Other observations

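The tests in this part were chosen after the results had been seen. The H4K12me1 peaks that remained or appeared after KMT9a knockdown clustered next to large assembly gaps, which mostly adjoin centromeres. Chromosome 9 held 711 of the 2843 knockdown peaks, 545 of them within 5 Mb of a gap of at least 1 Mb; chromosome 7 followed with 158 such peaks, chromosome 1 with 105, chromosome 16 with 104 and chromosome 15 with 94. The highest-scoring knockdown peaks lay on chromosome X (61726217 to 61734875), chromosome 12 (34832957 to 34840385) and chromosome 16 (33970596 to 33979892). H4K12me1 control peaks were densest on chromosomes 19 (58.1 per Mb) and 17 (41.3 per Mb) and scarce on chromosome 13 (1.95 per Mb). Their density did not simply follow gene density. Chromosome 22, with 12.7 genes per Mb, had 13.3 peaks per Mb, and chromosome 14, with 6.98 genes per Mb, had 37.6. Within chromosome 19, the 5 Mb bin starting at 15000001 held 680 peaks and 147 genes. The bin starting at 40000001 held 9 peaks and 144 genes. Over 547 bins of 5 Mb, the Spearman correlation of H4K12me1 control peaks was 0.94 with KMT9b, 0.90 with KMT9a and 0.86 with H4K20me3 in control cells, as high with the knockdown lists of KMT9b (0.94), KMT9a (0.94) and H4K20me3 (0.89), 0.64 with GC content and 0.27 with the H4K12me1 knockdown list. These correlations are across bins and not across replicates.

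Peaks of all 8 lists were dense on chromosome 10 from 45 to 85 Mb, a segment with ZSWIM8, ANXA7, SYNPO2L, HNRNPH3, RPS24, RHOBTB1, NRBF2, HK1, MRPS16 and PRF1, several of the genes with the widest or highest peaks. KMT9b in control cells had 94.4 peaks per Mb inside the segment and 4.54 on the rest of the chromosome. Gene density or GC content was excluded as the cause, since the segment has fewer genes per Mb (4.84 against 5.75), a lower GC content (40.5% against 42.1%) and, even in the list with the smallest excess, 2.51 times as many peaks per gene. The excess per Mb ran from 2.11 for H4K20me3 after knockdown to 20.8 for H4K12me1 after knockdown and for KMT9b in control cells. A shared step also occurred elsewhere. On chromosome 1, the bin starting at 170000001 held 109 H4K12me1, 136 H4K20me3, 62 KMT9a and 249 KMT9b control peaks. The bin starting at 175000001 held 1, 15, 6 and 5 in the same order. As all lists share the excess, it is not evidence of binding by any single antibody target. Input libraries were not analysed, so whether it is also present without an antibody is unknown. No other explanation was tested.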
